A study of Homo sapiens with 6 samples.

How the data were processed

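RNA was measured by polyA-selected, strand-specific sequencing in 6 libraries of SNU-449, an established human hepatocellular carcinoma cell line. Per the labels, 3 libraries came from cells stably expressing the wild-type tyrosine kinase Yes (Yes WT) and 3 from cells stably expressing the gatekeeper mutant Yes T348I. All 6 were treated with the kinase inhibitor dasatinib at 100 nM, and no untreated library was analysed here. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

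The deposited values are raw counts of reads per gene, 1 file per library, with gene identifiers of Ensembl. The submitters' processing notes name CASAVA 1.8.2, Trimmomatic 0.35, STAR 2.5.1b and the GRCh38 build, without roles or order. The layout of the deposited count files, with 4 summary lines and 3 columns of counts (unstranded, forward and reverse strand), is the one STAR writes. The annotation release behind the counts is not given in the sources used here. The reverse-strand column was used, since the kit keeps strand and the forward column held only 6.35% ± 0.21 (SD, n = 3) of the reverse-strand total in Yes WT and 6.26% ± 0.11 (SD, n = 3) in Yes T348I. The summary lines stayed out of library sizes and tests. Of the uniquely mapped reads, those on no annotated exon of the counted strand made up 7.69% ± 0.25 (SD, n = 3) in Yes WT and 6.61% ± 0.25 (SD, n = 3) in Yes T348I. These include reads on exons of the opposite strand only. Reads that fit more than 1 gene made up 3.11% to 3.15% per library. Reads that mapped to several places were not counted by the authors, which lowers the counts of genes with close copies.

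The files held 58219 gene identifiers. A table of gene names gave a symbol for 42249 of them, and 57836 were found in GENCODE release 29, from which biotypes and GRCh38 positions were taken. The total over genes ranged from 14360137 counts (Yes WT replicate 2) to 19608763 (Yes T348I replicate 1). Levels are given as CPM, normalised for library size, and genes of under 1 CPM rest on few reads.

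Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10), which left 14723, libraries were scaled by TMM, and a quasi-likelihood F-test compared Yes T348I with Yes WT with no covariate. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. A second count added a minimum change of 2-fold. Fold changes are Yes T348I over Yes WT, standard errors (SE) are of the log2 fold change, and CPM values are TMM-scaled. The test was also run on data simulated from the means, spreads and library sizes of this comparison. It recovered 50.7% of 67 genes changed 1.2-fold, 82.1% of 67 changed 1.5-fold and 93.9% of 66 changed 2-fold. Of its 195 calls over 14511 genes, 12 were false. Besides these genes only 1 list was changed, far fewer than the 8147 genes called in the data. The rates therefore need not hold for the data.

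Before the data were examined, 30 pathway lists and 5 marker lists were fixed, together with the tests and the rule for the genes named. The pathway lists covered YAP/TAZ-TEAD targets, Hippo pathway components, MRTF-SRF targets, ERK output, immediate early genes, dasatinib target kinases, receptor tyrosine kinases and ligands, focal adhesion, extracellular matrix, matrix proteases, G1/S, G2/M, BCL2 family, epithelial, mesenchymal, hepatocyte and oncofetal genes, type I interferon, NF-kB, STAT3, TGF-beta, Wnt, Notch, cholesterol synthesis, hypoxia, ATF4, endoplasmic reticulum chaperones, p53, NRF2 and ribosomal proteins. The marker lists were for leukocytes, endothelium, stellate cells and fibroblasts, cholangiocytes and polyadenylated nuclear RNAs. Each pathway list with at least 5 tested members was tested with camera of limma 3.58.1 on log2 CPM, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 30 lists. Camera with an estimated correlation and fry, which does not compare a list with other genes, were run beside it. On the simulated data, 1 list raised 1.3-fold passed camera and none of the other 29 did. Simulated genes were drawn independently of each other, so this does not show how often camera passes lists whose members are correlated.

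The genes named are YES1, YAP1 and WWTR1, then the 12 with the largest rise and the 12 with the largest fall among genes with a symbol, an adjusted p under 0.05, a mean of at least 1 CPM and no overlap between the groups, and then, for each list described, up to 4 members with the lowest adjusted p. Members of the marker lists are named as well. Other genes are named outside the rule, among them FGB, CPS1, FOXA2, MYOF and kinases that were not tested. Not all of these are marked as such where they appear. A few genes that the rule or the lists would name are not reported here.

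The alternatives were scaling by DESeq2 size factors, by upper quartile factors or by library size only, the Wald test of DESeq2 1.42.0, limma-voom, no low-count filter, a filter of at least 1 CPM in 3 libraries, the replicate number as a block, each library left out in turn, the unstranded column, protein-coding genes only, a threshold of 0.01, a test against a 1.2-fold change (glmTreat), and, for the lists, an estimated correlation, fry and members held by 1 list only. A smooth correction of each library for GC content and exonic length (loess, span 0.3) was added after the data were seen, and 99.8% of the tested genes had both values. The figures were drawn with matplotlib 3.10.9.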

Results

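Polyadenylated RNA was counted in 6 libraries of SNU-449 liver cancer cells, 3 from cells stably expressing wild-type Yes and 3 from cells stably expressing Yes T348I. Yes is a non-receptor tyrosine kinase of the SRC family, encoded by YES1, and dasatinib is an inhibitor of SRC family and ABL kinases. A change of the gatekeeper residue, which lines the drug pocket, is a common way to make a kinase insensitive to such an inhibitor. All libraries were from cells given 100 nM dasatinib. The comparison therefore asks which transcripts differ when the cells carry a Yes kinase altered at the gatekeeper position in the presence of the drug. Gene counts totalled 16117573, 14360137 and 14772150 in Yes WT replicates 1 to 3, and 19608763, 14937910 and 14392286 in Yes T348I replicates 1 to 3.

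YES1 itself (ENSG00000176105.13, GRCh38 chromosome 18, 721588 to 812546) was present at similar levels in both lines. Its mean was 364 ± 6.17 CPM (SD, n = 3) in Yes WT and 409 ± 26.2 CPM (SD, n = 3) in Yes T348I, a log2 fold change of 0.17 (SE 0.04, edgeR adjusted p = 9.94e-05). These counts can hold reads of the native gene and of the introduced one, and do not show the mutation. Among the 20 kinases listed as SRC family members or other dasatinib targets, 11 had enough counts to be tested. Of these, 4 rose and 4 fell, with the same 4 and 4 when adjusted over the list alone. EPHA2, an ephrin receptor, rose by a log2 fold change of 0.59 (SE 0.04, adjusted p = 9.57e-18) and ABL2 by 0.44 (SE 0.04, adjusted p = 2.17e-12). SRC fell by 0.54 on the log2 scale (SE 0.05, adjusted p = 1.94e-13), and the collagen receptor DDR1 fell by 0.59 (SE 0.05, adjusted p = 4.24e-14). The list as a whole did not pass the camera test (adjusted p = 0.88), and its median log2 fold change of 0.07 and its mean of -0.04 differed in sign, with camera on the higher side. FYN, LCK, FGR, BLK, KIT, PDGFRA, PDGFRB and CSF1R had at most 13 counts in any library and were not tested.

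The groups were clearly separated. The correlation of log2 CPM was 0.995 to 0.996 between libraries of a group (across genes, 6 pairs) and 0.982 to 0.985 between groups (9 pairs), and the first principal component, with 69.4% of the variance, parted the groups. No 2 libraries of a group agreed within counting noise, with a chi-square per degree of freedom of 1.48 to 5.20. Of the 14723 genes tested, 4123 were higher and 4024 lower in Yes T348I with an adjusted p under 0.05. In 59.5% of the genes the 3 values of each group did not overlap, where chance gives 10%. Most changes were small. The median change among the called genes was 1.27-fold, and 601 genes changed at least 2-fold, 129 upwards and 472 downwards (200 and 679 with no low-count filter). The biological coefficient of variation between replicates was only 2.83%, so that changes of this size passed the test. Against a minimum change of 1.2-fold, 1394 genes were higher and 1835 lower.

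**Figure D1:**
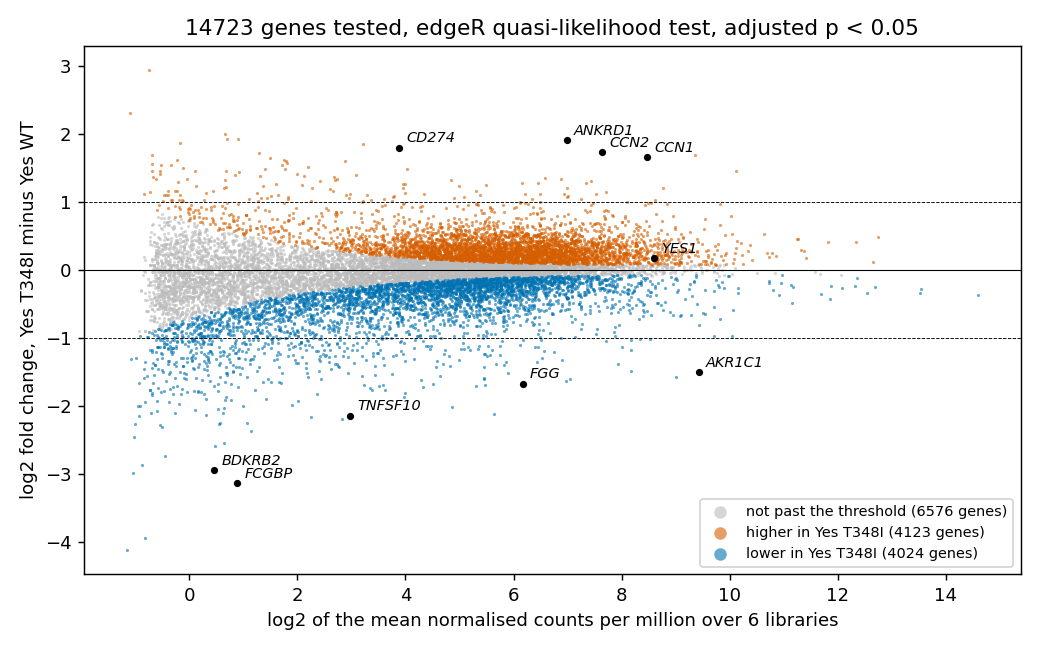
Each point is 1 of the 14723 genes tested, with the log2 of its mean normalised CPM over 6 libraries on the horizontal axis and its log2 fold change (Yes T348I minus Yes WT) on the vertical axis. Orange points were higher (4123 genes) and blue points lower (4024 genes), grey points did not pass, and dashed lines mark a change of 2-fold.

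ANKRD1, CCN2, CCN1 and CD274 were among the 12 largest rises. ANKRD1, a muscle ankyrin repeat protein (chromosome 10, 90912096 to 90921276), rose from 53.5 ± 2.48 to 201 ± 10.7 CPM (SD, n = 3 each), a log2 fold change of 1.90 (SE 0.04, adjusted p = 2.63e-32). The matricellular proteins CCN2 (chromosome 6, 131948176 to 131951373) and CCN1 (chromosome 1, 85580761 to 85583962) rose from 92.0 ± 2.95 to 306 ± 8.58 CPM and from 171 ± 10.6 to 540.4 ± 10.1 CPM. CD274, the immune checkpoint ligand PD-L1 (chromosome 9, 5450503 to 5470566), rose from 6.54 ± 0.243 to 22.9 ± 1.67 CPM, a log2 fold change of 1.79 (SE 0.09, adjusted p = 3.31e-20). The growth factor FGF1 rose from 3.65 ± 0.584 to 11.1 ± 0.497 CPM, and NOG, which encodes the BMP antagonist noggin, from 4.05 ± 0.461 to 14.6 ± 1.68 CPM. Among the rest of the 12 strongest, MYCT1, MMP3, PEAR1 and PLCE1-AS1 reached at most 5.08 CPM in Yes T348I.

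The 12 strongest falls were at low levels, with Yes WT means of 2.03 to 12.8 CPM. TNFSF10, which encodes the death ligand TRAIL (chromosome 3, 172505508 to 172523507), fell from 12.8 ± 0.759 to 2.95 ± 0.497 CPM, a log2 fold change of -2.14 (SE 0.13, adjusted p = 4.03e-18). TCP11L2 fell from 11.7 ± 1.24 to 2.53 ± 0.529 CPM, and the lipid transporters ABCA6 and ABCG1 fell by 2.16 (SE 0.17) and 2.54 (SE 0.30) on the log2 scale. FCGBP (chromosome 19, 39863323 to 39934626), an IgG-Fc binding protein of mucus, had the largest fall, from 3.33 ± 0.378 to 0.374 ± 0.0998 CPM, a log2 fold change of -3.14 (SE 0.29, adjusted p = 1.42e-12). The bradykinin receptor gene BDKRB2, the amino acid transporter gene SLC7A8, RAB17, STAR, BTBD19, HHIPL2 and LINC02870 completed the set, with log2 fold changes of -2.94 to -2.14.

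YAP/TAZ-TEAD target genes were higher as a group in Yes T348I. Of the 30 gene lists, 10 passed camera with the preset correlation and 1 with an estimated correlation. The 2 forms differ in more than the correlation. For the G1/S list the estimate was -0.017, below the preset, yet the unadjusted camera p went from 5.15e-14 to 0.0010. The lists that no longer passed therefore cannot be put down to correlation between genes alone. Other splits of the 6 libraries into 3 and 3, under which no gene was called, let 3 to 8 lists pass. Each of those splits mixed libraries of both lines and kept part of their difference, so 3 to 8 is not a rate of false passes. YAP and TAZ are transcriptional coactivators held in check by the Hippo pathway. Of 21 tested targets 17 rose and 3 fell, with the same numbers when adjusted over the list alone, and the median log2 fold change was 0.69 (camera adjusted p = 3.50e-07, adjusted p = 0.20 with an estimated correlation). Besides ANKRD1, CCN2 and CCN1, the receptor tyrosine kinase AXL rose from 262 ± 3.72 to 605 ± 5.75 CPM (log2 fold change 1.21, SE 0.03, adjusted p = 3.10e-30). The genes of the coactivators themselves moved little. YAP1 was at 166 ± 5.83 CPM in Yes WT and 159.6 ± 2.67 CPM in Yes T348I (log2 fold change -0.06, SE 0.04, adjusted p = 0.16), and WWTR1, which encodes TAZ, rose by a log2 fold change of 0.14 (SE 0.03, adjusted p = 4.97e-04). The difference of YAP1 passed the threshold when libraries were scaled by upper quartile factors (log2 fold change -0.10, adjusted p = 0.016), by library size only (-0.10, adjusted p = 0.023) or after the GC and length correction (-0.08, adjusted p = 0.033). Of 26 Hippo pathway components tested, 15 rose and 8 fell, with the same numbers adjusted over the list alone. AMOTL2, AJUBA and NF2 rose by log2 fold changes of 1.27, 1.04 and 1.07, and AMOTL1 fell by 0.91 on the log2 scale. AMOTL2 and NF2 encode restraints on YAP. The Hippo list did not pass camera (median log2 fold change 0.25, adjusted p = 0.079). It passed under 3 of 19 alternatives, which were limma-voom (camera adjusted p = 0.011), no low-count filter (camera adjusted p = 0.0040) and fry (adjusted p = 4.26e-04). Its camera adjusted p was 0.68 with an estimated correlation and at most 0.32 under the others. The Hippo and target lists share members, among them AMOTL2.

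**Figure D2:**
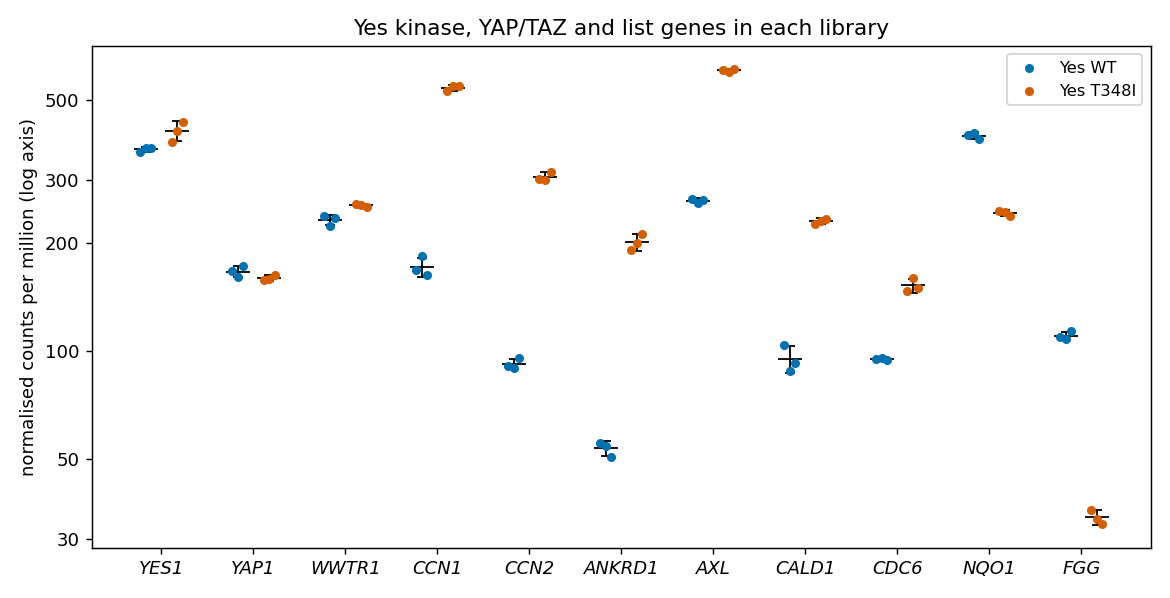
Normalised CPM (log axis) in each of 6 libraries for YES1, YAP1, WWTR1 and 8 genes of the lists, with the 3 Yes WT libraries in blue and the 3 Yes T348I libraries in orange. Horizontal marks and bars are the mean and SD (n = 3). CCN1, CCN2, ANKRD1, AXL, CALD1 and CDC6 were higher and NQO1 and FGG lower in every Yes T348I library, while YAP1 lay at 166 CPM in Yes WT and 159.6 CPM in Yes T348I.

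Targets of MRTF and SRF, which encode actins and actin-binding proteins, also rose. Of 21 tested, 18 rose and 1 fell, the same adjusted over the list alone, with a median log2 fold change of 0.45 (camera adjusted p = 3.50e-07, adjusted p = 0.28 with an estimated correlation). CALD1 (caldesmon) rose from 94.8 ± 8.29 to 229.6 ± 4.20 CPM, a log2 fold change of 1.27 (SE 0.04), TPM1 and TPM4 (tropomyosins) by 0.74 (SE 0.03) and 0.60 (SE 0.03), and TAGLN (transgelin) by 0.80 (SE 0.04). Of 29 focal adhesion and integrin genes, 17 rose and 7 fell (19 and 7 adjusted over the list alone), with a median log2 fold change of 0.17 (camera adjusted p = 0.0096, adjusted p = 0.38 with an estimated correlation). After the GC and length correction 20 rose and 5 fell, with a median of 0.26. CAV1 rose by a log2 fold change of 0.79 (SE 0.03), ZYX by 0.66 (SE 0.04) and ACTN1 by 0.51 (SE 0.03), while the integrin gene ITGB5 fell by 0.59 (SE 0.04). Extracellular matrix genes split, with 11 of 27 higher and 14 lower (11 and 15 adjusted over the list alone, camera adjusted p = 0.45). THBS1 rose by a log2 fold change of 1.45 (SE 0.03), though it overlaps another gene on its strand, and THBS2, COL1A2 and COL3A1 fell by 0.67 (SE 0.03), 0.63 (SE 0.03) and 0.76 (SE 0.05). Of 18 matrix proteases and inhibitors 5 rose and 7 fell, the same adjusted over the list alone (camera adjusted p = 0.88), with the median of -0.0034 and the mean of 0.13 differing in sign. ADAMTS1 rose by a log2 fold change of 1.26 (SE 0.08), and MMP14 and CTSL fell by 0.76 (SE 0.05) and 0.54 (SE 0.03).

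Cell cycle genes were higher in Yes T348I. Of 30 G1/S and DNA replication genes tested 29 rose and none fell, also when adjusted over the list alone, with a median log2 fold change of 0.48. Of the 30 pathway lists, this was the only one past the threshold under both forms of camera (adjusted p = 1.55e-12, adjusted p = 0.031 with an estimated correlation). The replication licensing factor CDC6 rose to 152 ± 6.70 CPM (SD, n = 3), a log2 fold change of 0.68 (SE 0.04, adjusted p = 1.51e-18). MCM10, UHRF1 and MCM4 rose by 0.69 (SE 0.04), 0.74 (SE 0.05) and 0.51 (SE 0.03). Of 32 G2/M and mitosis genes 27 rose and none fell (28 adjusted over the list alone), with a median log2 fold change of 0.26 (camera adjusted p = 1.48e-07, adjusted p = 0.30 with an estimated correlation). CDC20, ANLN, CCNA2 and AURKB rose by 0.64 (SE 0.04), 0.60 (SE 0.03), 0.53 (SE 0.04) and 0.57 (SE 0.05). Of 40 ribosomal protein genes 20 rose and 1 fell, the same adjusted over the list alone, by little. Their median log2 fold change was 0.08 (camera adjusted p = 0.0092, adjusted p = 0.68 with an estimated correlation), RPL35, with the lowest adjusted p, rose by 0.26 (SE 0.03), and their many pseudogenes make such small differences uncertain. The ribosomal list no longer passed with upper quartile factors (median log2 fold change 0.035, camera adjusted p = 0.058) or library size only (median 0.038, camera adjusted p = 0.052).

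The fibrinogen genes FGG and FGA and most tested NRF2 antioxidant genes were lower. Only 10 of the 30 hepatocyte genes had enough counts to be tested, and 8 of them fell and none rose, also when adjusted over the list alone (median log2 fold change -0.99, camera adjusted p = 0.0050, adjusted p = 0.30 with an estimated correlation). The fibrinogen chains FGG and FGA fell from 109.9 ± 2.93 to 34.3 ± 1.59 CPM and from 24.9 to 7.01 CPM, log2 fold changes of -1.67 (SE 0.05) and -1.80 (SE 0.09). AMBP fell by 1.89 (SE 0.21). The better expressed members FGB and CPS1 fell by only 0.21 (SE 0.05) and 0.20 (SE 0.05) from 60.5 and 53.4 CPM, and FOXA2 did not pass (log2 fold change 0.03, 25.9 CPM), while the other members that fell had Yes WT means of 1.48 to 4.19 CPM. The median of this list was -0.49 with no low-count filter, when more members of few counts entered. Of 15 NRF2 targets 11 fell and 2 rose, the same adjusted over the list alone (median log2 fold change -0.45, camera adjusted p = 5.03e-04, adjusted p = 0.30 with an estimated correlation). The quinone reductase gene NQO1 fell from 398 to 242 CPM (log2 fold change -0.72, SE 0.03), and AKR1B10 fell from 14.4 to 4.37 CPM (adjusted p = 1.01e-16). AKR1C1 fell by 1.51 (SE 0.04), but shares sequence with its close copies and is uncertain. Of 14 endoplasmic reticulum chaperone genes 10 fell and none rose (11 adjusted over the list alone), with a median log2 fold change of -0.15 (camera adjusted p = 0.0096, adjusted p = 0.38 with an estimated correlation). SEL1L, DNAJB9, HERPUD1 and HSP90B1 fell by 0.33 (SE 0.04), 0.52 (SE 0.06), 0.38 (SE 0.05) and 0.17 (SE 0.03). Of 10 Wnt/beta-catenin targets 5 fell and 1 rose, the same adjusted over the list alone (median log2 fold change -0.28, camera adjusted p = 0.043, adjusted p = 0.45 with an estimated correlation). BMP4 fell by 1.24 (SE 0.06), DKK1, which encodes a secreted Wnt antagonist, by 0.82 (SE 0.03), and GLUL by 0.24 (SE 0.04). The Wnt list passed the threshold by little, and its adjusted p was 0.054 without Yes WT replicate 2, 0.10 without Yes WT replicate 3 and 0.054 without Yes T348I replicate 3. It was 0.058 with upper quartile factors, 0.052 with library size only and 0.057 with the replicate number as a block.

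**Figure D3:**
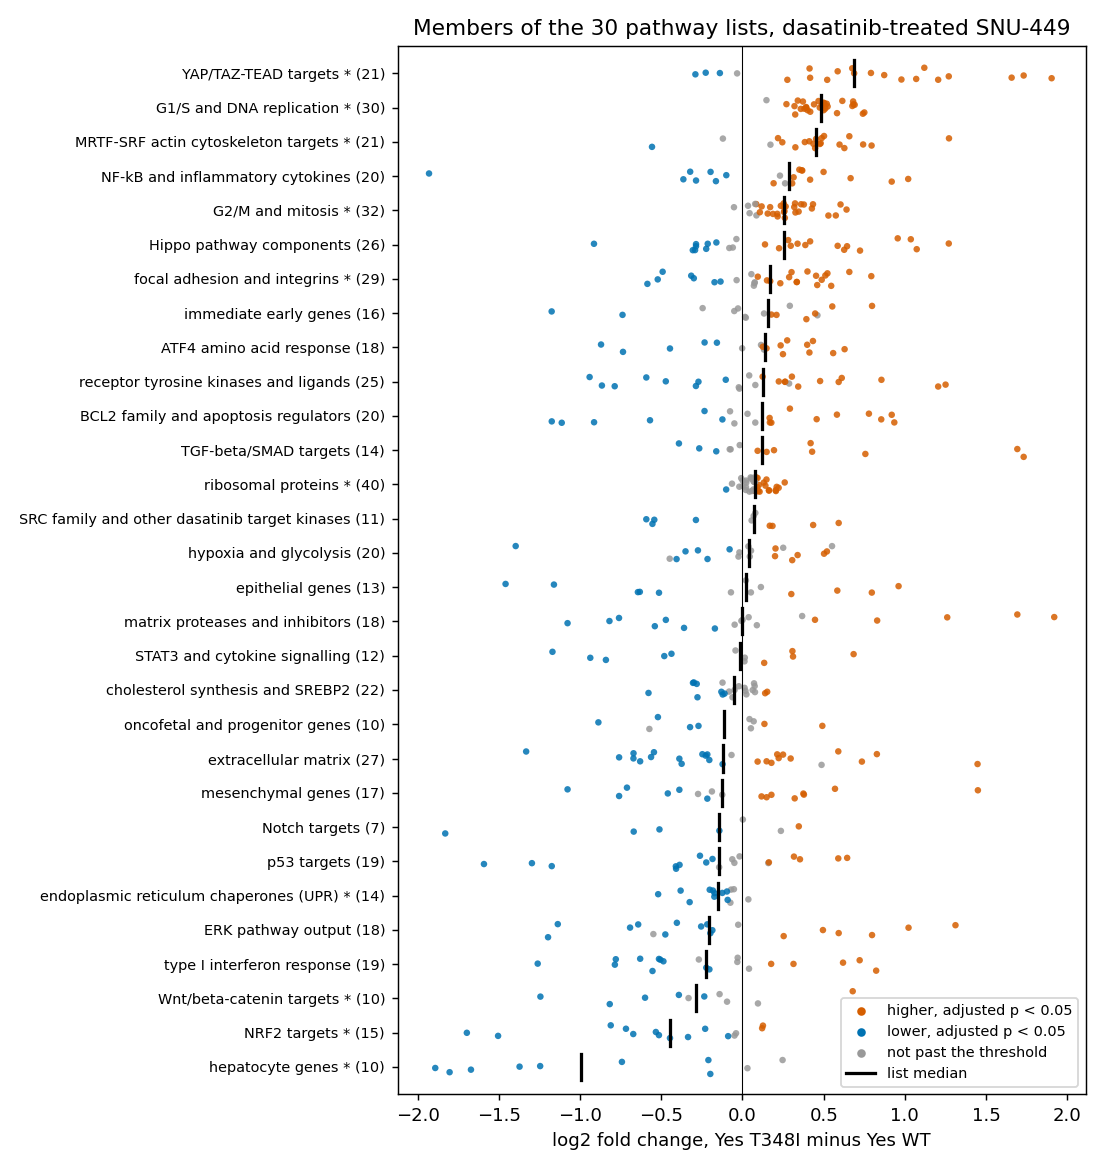
Each point is a tested member of 1 of 30 gene lists, placed by its log2 fold change (Yes T348I minus Yes WT), in orange if higher and in blue if lower with an adjusted p under 0.05, and otherwise in grey. Black bars are list medians, from 0.69 for YAP/TAZ-TEAD targets to -0.99 for hepatocyte genes, asterisks mark the 10 lists past the camera threshold with the preset correlation, and the number tested is in brackets.

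Signalling lists closer to receptors and ERK moved in both directions. Of 18 genes of the ERK output list 6 rose and 10 fell, the same adjusted over the list alone (median log2 fold change -0.21, camera adjusted p = 0.34). FOSL1 and the cyclin gene CCND1 rose by log2 fold changes of 1.31 (SE 0.04) and 1.02 (SE 0.03), while the ERK feedback inhibitor SPRY4 fell by 1.14 (SE 0.04) and ETV1 fell from 131 to 57.1 CPM (adjusted p = 6.92e-26). Of 16 immediate early genes 6 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.31), with JUN, KLF6 and KLF10 higher by 0.55 (SE 0.04), 0.39 (SE 0.03) and 0.45 (SE 0.05) and NR4A2 lower at -1.18 (SE 0.10). Of 25 receptor tyrosine kinases and ligands 12 rose and 8 fell, the same adjusted over the list alone (camera adjusted p = 0.25). HBEGF, EGFR and PDGFB rose by 1.25 (SE 0.06), 0.61 (SE 0.04) and 0.86 (SE 0.05). Of 20 BCL2 family and apoptosis regulators 10 rose and 6 fell, the same adjusted over the list alone (camera adjusted p = 0.44). The apoptosis inhibitors BIRC2, BIRC3 and BCL2L1 rose by 0.85 (SE 0.04), 0.92 (SE 0.05) and 0.58 (SE 0.04), and BMF, which encodes a pro-apoptotic member, fell by 1.11 (SE 0.06).

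Of 19 p53 targets 5 rose and 9 fell (camera adjusted p = 0.23). TP53INP1 fell by 1.59 (SE 0.06) on the log2 scale and GDF15 fell to 0.407 of its Yes WT level (adjusted p = 1.04e-24). Of 20 NF-kB and inflammatory cytokine genes 11 rose and 7 fell (camera adjusted p = 0.19, but 0.018 without a low-count filter), with LIF and NFKB1 higher by 0.36 (SE 0.03) and 0.50 (SE 0.05) and ICAM1 lower at -0.32 (SE 0.03). Of 19 type I interferon genes 5 rose and 10 fell (camera adjusted p = 0.23), with STAT2 and IFIT3 lower at -0.78 (SE 0.05) and -0.79 (SE 0.07) and IFIH1 higher at 0.72 (SE 0.06). Of 12 STAT3 and cytokine signalling genes 4 rose and 5 fell (camera adjusted p = 0.62), and BCL6, BCL3 and CEBPD fell by 1.17 (SE 0.06), 0.94 (SE 0.06) and 0.84 (SE 0.06). Adjusted over each of these 4 lists alone, the numbers were the same. The remaining lists, with higher and lower members, were TGF-beta targets (8 and 3 of 14, camera adjusted p = 0.19, but 0.048 after the GC and length correction and 0.019 without a low-count filter), Notch targets (1 and 4 of 7, adjusted p = 0.39), cholesterol synthesis (2 and 8 of 22, adjusted p = 0.33), hypoxia and glycolysis (6 and 6 of 20, adjusted p = 0.86), ATF4 response (10 and 5 of 18, adjusted p = 0.25), epithelial genes (4 and 5 of 13, adjusted p = 0.94), mesenchymal genes (8 and 6 of 17, adjusted p = 0.94) and oncofetal genes (2 and 4 of 10, adjusted p = 0.54). Adjusted over each list alone these numbers were the same except for oncofetal genes, with 5 lower. Median and mean differed in sign for the epithelial (0.02 and -0.13) and hypoxia lists (0.04 and -0.01), and the mesenchymal list had a median of -0.12 and a mean of -0.04 while camera placed it on the higher side.

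Leukocyte and endothelial markers were near the floor, while some markers of stellate cells, fibroblasts and cholangiocytes were well above it. Whether the line itself expresses the latter was not tested. Of 9 stellate cell and fibroblast markers 5 reached a group mean of 1 CPM, and of 7 cholangiocyte markers 4 did. Among those that did not, DCN and LUM had group means of at most 0.0464 and 0.0705 CPM, and CFTR and EPCAM of at most 0.0204 and 0.506 CPM. Of 12 leukocyte markers only CD14 was tested, at 2.43 ± 0.279 CPM in Yes WT and 0.721 ± 0.467 CPM in Yes T348I (adjusted p = 5.09e-06), and of 10 endothelial markers only PECAM1, at most at 0.847 CPM (log2 fold change -2.00, adjusted p = 5.09e-04). Of 5 tested stellate cell and fibroblast markers 2 rose and 2 fell, with RGS5 at 132 and 145 CPM. Of 5 tested cholangiocyte markers 3 rose and 1 fell. KRT7 and SOX9 rose by log2 fold changes of 0.96 (SE 0.04) and 0.49 (SE 0.04), and SPP1, which encodes osteopontin, fell by 0.98 (SE 0.03).

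The nuclear RNAs MALAT1 and NEAT1, listed as a sign of RNA quality, both fell in Yes T348I along with the gene groups above, by 0.98 (SE 0.05) and 1.02 (SE 0.03) on the log2 scale. Of 1333 long non-coding genes tested, 137 rose and 312 fell, and the others did not pass. Of 12390 protein-coding genes 3901 rose and 3608 fell, a balance that turned with upper quartile factors (3371 and 4158) and library size only (3375 and 4065). The difference between these classes was not tested. Mitochondrial genes held 10.2% ± 0.53 of the counts in Yes WT and 8.10% ± 0.86 in Yes T348I (SD, n = 3 each). With 3 libraries against 3, the exact two-sided permutation p of this difference was 0.1, the smallest the design allows. Of 24 mitochondrial genes tested, 14 fell and none rose, also with DESeq2 size factors, upper quartile factors and library size only, while 2 rose and 12 fell of 25 tested without Yes T348I replicate 1, and 8 fell in the Wald test of DESeq2. The share of uniquely mapped reads on no annotated exon of the counted strand was also lower in Yes T348I, by 1.08 percentage points (exact two-sided permutation p = 0.1). For reads outside exons on either strand the difference was -0.93 percentage points (exact two-sided permutation p = 0.1).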

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

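The tests of sample splits and of growth state below were chosen after the results were seen, and the GC and length correction was added after the data were seen. Bootstrap intervals here and below resample genes and not libraries. They treat genes as independent and do not measure the spread between libraries or cultures.

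Reads on the strand opposite to a gene are outside the comparisons of the report. Of 1833 tested genes with no annotated gene on their opposite strand, the opposite strand held a median of 1.71% of the sense reads, and 79 genes had at least 20%. In 4 of these 79 the opposite strand was higher in Yes T348I and in 9 it was lower, and those named here were chosen after their values were seen. The strand opposite to the long non-coding gene MIR137HG (chromosome 1, 97933474 to 98049863) had 1.52 ± 0.308 CPM in Yes WT and 5.87 ± 0.834 CPM in Yes T348I (SD, n = 3 each, edgeR log2 fold change 1.95, adjusted p = 6.69e-12), which was 36.9% and 125% of the sense reads. Its nearest annotated gene on that strand, NFU1P2, lay 27137 bp away and was not tested. The strand opposite to CCDC85B had 7.82 CPM in Yes WT and 16.6 CPM in Yes T348I, and FOSL1, 414 bp away on that strand, rose by a log2 fold change of 1.31. Opposite to TGFB2-AS1 there were 8.48 and 16.3 CPM, and TGFB2, 557 bp away, rose by 0.87. Opposite to FOXD2 there were 1.97 and 3.41 CPM, and FOXD2-AS1, 1376 bp away, rose by 0.55. The 9 lower ones had log2 fold changes of -2.25 to -0.97 from Yes WT levels of 0.762 to 7.41 CPM, with the largest fall opposite to SPAG4 (4.14 and 0.842 CPM) and the highest levels opposite to MTX1P1 (7.41 and 3.74 CPM) and ANXA9 (6.83 and 2.66 CPM). What these reads are was not tested.

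The number of changed genes was 8147, of which 601 changed at least 2-fold. The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05: the real split gave 8147 and 601 genes and the highest other split gave 0 and 0, so that in each case 1 split gave as many. For gene lists past camera, likewise 1 split of 10 gave as many as the real one, with 10 lists, and the highest other split gave 8. Each of the other splits mixed libraries of both lines. The difference between the lines thus lay partly within their groups and partly between them. Their counts are therefore not those of a comparison free of that difference. After the GC and length correction 92.1% of the calls (7502) were kept in the same direction, which argues against such a trend as the whole cause. A difference between the 2 stable lines that arose apart from the mutation was not tested and may follow the groups as closely as the mutation does.

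The rise of YAP/TAZ-TEAD targets was little altered by the GC and length correction, with a median log2 fold change of 0.74 (95% bootstrap interval 0.46 to 1.05, 21 genes) against 0.69 before. The mean of the neighbours' medians was 0.016 (95% bootstrap interval -0.03 to 0.06). This argues against copy number differences that reach the neighbours as the cause for the 21 targets as a set. It does not for MYOF, whose neighbours had a median of 0.30 against 0.41 for MYOF itself. Differences limited to the targets themselves would not show in the neighbours. Growth state or density of the cultures stays open, since the G1/S list also rose (median log2 fold change 0.48, 95% bootstrap interval 0.40 to 0.51) and density, which could move both lists, is not in the labels. An effect of the mutant kinase under dasatinib also stays open, with no untreated libraries analysed here to separate it from a difference between the lines.

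Reads outside exons were fewer in Yes T348I, and long non-coding genes fell more often than they rose. Genomic DNA in the Yes WT libraries could not be excluded: olfactory receptor genes had 1.10 times the reads per unique read in Yes WT as in Yes T348I (95% interval 0.775 to 1.56 for counting error only, 383 genes with 69 and 67 reads, 26.3% of them from OR2B6), an interval that holds both 1 and 1.19, the ratio of the pooled shares of reads outside exons on either strand (group means 6.03% ± 0.214 in Yes WT and 5.10% ± 0.178 in Yes T348I, SD, n = 3 each). Less unspliced RNA in Yes T348I also stays open. Sense-intronic genes differed from their host genes by a median log2 fold change of -0.091 (95% bootstrap interval -0.26 to 0.05, 61 genes). The bound set before this result, an interval that holds 0, was to count against unspliced RNA, but it was wrong, because the interval also holds -0.25, the log2 ratio of those either-strand shares, and the reading was changed after the result was seen.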

How the results depend on the processing

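The GC and length correction was the one alternative chosen after the data were seen. The count of 8147 changed genes lay between 6656 (DESeq2) and 8328 (GC and length correction) over the alternatives except the test against a 1.2-fold change, which by its construction left 3229 genes, 1394 higher and 1835 lower. No call turned its direction under the other alternatives, and 2 did under the GC and length correction. With upper quartile factors 43.5% of the calls were higher, against 50.6%. Leaving out each library in turn gave 7351 to 7883 genes, and 664 to 747 changed at least 2-fold. With no low-count filter 200 genes were at least 2-fold higher, against 129; the cause was not tested.

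Replicate numbers did not pair the libraries: the deviations of same-numbered libraries correlated at -0.03, 0.001 and -0.02, and those of Yes WT replicate 3 and Yes T348I replicate 1 highest, at 0.04. With the number as a replicate block, 7990 genes and 9 lists passed, and the Wnt list did not (adjusted p = 0.0570).

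Of the 30 lists, 10 passed camera, 1 (G1/S, adjusted p = 0.031) with an estimated correlation, and 25 passed fry, which asks a different question. With an estimated correlation the adjusted p was 0.203 for YAP/TAZ-TEAD targets, 0.277 for MRTF-SRF targets, 0.377 for focal adhesion and for endoplasmic reticulum chaperones, 0.302 for G2/M, hepatocyte and NRF2 genes, 0.447 for Wnt targets and 0.680 for ribosomal proteins. For YAP/TAZ-TEAD targets the adjusted p ranged from 1.10e-11 to 0.203 over 19 alternatives, and without the estimated correlation it was at most 2.48e-04. The Wnt and ribosomal lists did not pass with upper quartile factors (0.0578 each) or library size only (0.0516 each), and the cause was not tested. The Wnt list ranged from 0.0256 to 0.10 with 1 library left out, and did not pass without Yes WT replicate 2 (0.0540), Yes WT replicate 3 (0.10) or Yes T348I replicate 3 (0.0538). Over the camera alternatives its adjusted p lay between 0.0164 (no low-count filter) and 0.447, and it was 9.50e-04 by fry. Lists outside the 10 passed in 20 cases, 15 of them under fry.

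YES1 passed under all 17 alternatives (log2 fold change 0.10 to 0.22). Of 2695 values of named genes under alternatives, 15 no longer passed, 4 newly passed and none reversed. COL1A1 did not pass without Yes WT replicate 2 (adjusted p = 0.0532), nor ACTA2 with unstranded counts (0.0859). HLA-DMA did not pass without Yes WT replicate 2 (0.275) or Yes T348I replicate 1 (0.0738), and B2M did not without Yes WT replicate 2 (0.133), Yes WT replicate 3 (0.158), Yes T348I replicate 1 (0.316) or Yes T348I replicate 3 (0.0953). Genes of few counts, among them 20 hepatocyte genes, were not tested, and whether depth or absence of their RNA kept them low was not tested.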

Other observations

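The FOXO and interferon gamma lists and the neighbour test of CD274 were chosen after the strongest changes were seen, and their genes lie outside the rule for named genes.

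FOXO target genes, which include cell cycle inhibitors and catabolic genes, were lower in Yes T348I. The list left out genes already seen among the strongest changes. All 17 tested members fell, with a median log2 fold change of -0.73. The same 17 of 17 fell under DESeq2 size factors, upper quartile factors and library size only. The unadjusted camera p was 2.30e-09 (adjusted p = 4.59e-09), and 0.0030 with an estimated correlation (adjusted p = 0.0060). Camera p-values of this paragraph were adjusted over the FOXO and interferon gamma lists only. They are therefore not comparable with the adjusted p-values of the pathway lists, which were adjusted over more lists. PDK4, which encodes an inhibitor of pyruvate dehydrogenase, fell by 1.42 (SE 0.07), CCNG2 fell by 1.23 (SE 0.06), PIK3IP1 fell by 1.25 (SE 0.20), KLF9 fell by 1.02 (SE 0.13) and CDKN1B, which encodes the cyclin-dependent kinase inhibitor p27, fell by 0.55 (SE 0.06) on the log2 scale. GADD45A, also known as a FOXO target, was not on the list and rose by 1.07 (SE 0.06, edgeR adjusted p = 4.92e-18), and with it 17 of 18 fell and 1 rose (median log2 fold change -0.71, camera adjusted p = 1.33e-07, adjusted p = 0.0086 with an estimated correlation), a test chosen after its value was seen. Lower FOXO activity in Yes T348I is a hypothesis that the list test is in line with, and no activity was measured.

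PDCD1LG2, which encodes the checkpoint ligand PD-L2 and lies near CD274 (chromosome 9, 5510570 to 5571254), rose with it, from 3.54 ± 0.428 to 9.29 ± 1.75 CPM (SD, n = 3 each, log2 fold change 1.37, SE 0.15, edgeR adjusted p = 9.26e-11). An interferon gamma response was tested as a candidate explanation. A list of interferon gamma and antigen presentation genes without this pair lay on the lower side (adjusted p = 0.101 over both lists). It had 3 of 19 tested members higher (GBP1 at 0.81, TAP1 at 0.32 and TAP2 at 0.34) and 10 lower, among them IRF1 at -0.36, which argues against a rise of the list as a whole. Of the 10 lower members, B2M lost its call under 9 alternatives (adjusted p 0.0535 to 0.341), HLA-DMA under 3 (0.0738 to 0.275) and HLA-C under the GC and length correction (0.107). The 20 tested neighbours of CD274, with PDCD1LG2 left out, had a median log2 fold change of -0.018 (95% bootstrap interval -0.14 to 0.29). This argues against a copy number difference of the wider region. A difference limited to CD274 and PDCD1LG2 would not show in these neighbours and was not tested.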
